A study of Danio rerio with 4 samples.

How the data were processed

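Kidney marrow, the main blood-forming organ of adult zebrafish, was measured by droplet single-cell RNA sequencing in 4 libraries, 1 per genotype. The genotypes were wild type, c-myb hyper, pu.1 G242D/G242D and the double mutant that carries both alleles. Per the labels' protocols, marrow of 1-year-old fish was dissociated by pipetting and strained, and libraries were made with a 3' gene expression kit. The number of fish per library is not stated.

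The deposited values are UMI counts per gene and barcode. Per the submitters' processing notes, the authors used Cell Ranger 3.1.0 and Seurat 3.1.1 with genome build GRCz11, whereas per the file headers the matrices were written by cellranger 5.0.0. The notes do not say which step each tool made, and no cell annotation was used here. Each library came as a sparse matrix and as a dense table. Both held the same count for all 27429 genes and every barcode of each library. Counts were used as deposited. Gene symbols were those paired with the identifiers in the files: 27429 identifiers carried 26776 symbols, and counts of the 517 symbols with more than 1 identifier were summed. Of the identifiers, 24988 were found in the reference name table, 10568 of them with the same symbol, and no coordinates were used because the reference assembly, GRCz12tu, differs from the build of the files.

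Every deposited barcode held at least 500 UMIs, a limit set before deposit. Barcodes were kept with at least 200 genes and at most 15% mitochondrial UMIs. Doublets were scored with scrublet in each library. Its own threshold marked 203 barcodes of wild type and 62 of pu.1 G242D/G242D, and 0 in both c-myb hyper libraries. There the planned fallback removed the highest scores at a rate of 0.8% per 1000 barcodes, 1265 barcodes in c-myb hyper and 1159 in the double mutant. The libraries were thus treated unequally, and alternatives with doublets kept and with 1 rule for all libraries were run. The kept cells numbered 9900, 11309, 9328 and 10875 in wild type, c-myb hyper, pu.1 G242D/G242D and double mutant.

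Cells of all libraries were normalized to 10000 UMIs, log-transformed and clustered together (2000 variable genes, 40 principal components, 20 nearest neighbours, Leiden resolution 1) without batch integration, because library and genotype are the same thing here. A cluster was called by a class name, as "X-like", when at least 3 markers of that class lay among its top 30 genes and its leading genes did not go against the name. Clusters 12, 15, 16, 18, 20, 25 and 30 stayed unnamed. No cluster met the rule for stem and progenitor cells: cluster 16 held 3 of their markers but 2 macrophage markers among its top 10 genes, so its cells are compared by number, in place of the progenitor class that had been planned. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

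Class shares are of all kept cells, with exact Clopper-Pearson 95% intervals. For expression, UMIs of all cells of a class were summed per library and divided by the class total and scaled to 1000000 (CPM), with exact Poisson intervals, and ratios have exact conditional-binomial intervals. Classes with at least 50 cells in both libraries were compared. With 1 library per genotype there are no replicates, so no test between genotypes was made, no p-value is given, and all intervals cover counting error only. Against a count of 0, a floor of 3 counts was used. The departure of the double mutant is its log2 value minus those of both c-myb hyper and pu.1 G242D/G242D plus that of wild type, so 0 is the product of the effects of each allele.

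The markers, 21 gene lists, the named-gene rule and most alternatives were written before the data were examined. The alternatives added after seeing the data are named in the closing section. Of 465 list symbols 448 were found in the files, and of 439 marker symbols 393. A list member is measured at a CPM of at least 10 in any library, and is counted as higher or lower at 1.5-fold with an interval that excludes 1. A list's median log2 ratio is given with its percentile among 10000 random lists of its size matched on mean expression in 20 bins. Named genes are the 10 highest and the 10 lowest against wild type in each mutant, ranked by the interval bound nearest to 1, among genes with a CPM of at least 50 in either library, and the 5 highest and 5 lowest in the double mutant against all 3 other libraries. Symbols of clones and automatic models, ribosomal, mitochondrial, hemoglobin and immunoglobulin genes were left out of that ranking. The targeted genes myb, spi1b and spi1a (both fish copies of the gene for Pu.1) and lbr are given always.

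The ratio step was tested on simulated data, for c-myb hyper over wild type in neutrophil-like cells with 5415 genes. Of 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, the interval excluded 1 on the right side for all, and among 5215 unchanged genes it excluded 1 for 4.60%. In a further draw without changed genes, the ratios of lists of 16 genes were shifted 1.5-fold. Then 40 of 40 shifted lists lay above the central 95% of random lists, and 35 of 40 unshifted lists lay within it. Only counting noise was simulated, so this does not show how the percentiles behave with the wider spread between the real libraries.

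Alternatives to the cell filter, doublets, resolution, joint clustering, denominator, scaling, free RNA, weight of cells, depth and the minimum for list members were run one at a time. For free RNA, the summed profile of the library was subtracted from the class, scaled by the hemoglobin UMIs of that class. Expression was not compared in thrombocyte-like cells, which numbered 22 in c-myb hyper and 30 in the double mutant.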

Results

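Gene expression was measured in single cells of the kidney marrow of adult zebrafish, with 1 library from each of 4 genotypes. The wild-type library held 10632 barcodes and 102290597 UMIs, the c-myb hyper library 12999 barcodes and 92502117 UMIs, the pu.1 G242D/G242D library 9651 barcodes and 95946242 UMIs, and the double mutant 12400 barcodes and 85643475 UMIs. The median kept cell had 5742, 4517, 5386 and 5056 UMIs in that order, and 1070, 1135, 1336 and 1219 genes. Every genotype is 1 library, so no difference below has a replicate check, and all intervals are 95% intervals of counting error only. Both alleles concern transcription factors of blood cells, c-Myb and Pu.1, and the title of the series concerns their joint part in an anomaly of the neutrophil nucleus and in leukemia. Each mutant is therefore set against wild type and the double mutant against both others.

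The gene myb (ENSDARG00000053666), which encodes c-Myb, was higher in both libraries labelled c-myb hyper. In neutrophil-like cells it stood at 73.7 CPM in wild type (69.6 to 78.0), 392 in c-myb hyper (385 to 398), 89.7 in pu.1 G242D/G242D (86.6 to 93.0) and 1067 in the double mutant (1057 to 1077). This was 5.32-fold (5.01 to 5.65) and 14.5-fold (13.6 to 15.4) above wild type in c-myb hyper and the double mutant. It was also highest in the double mutant and next in c-myb hyper in macrophage-like cells (12.1, 88.6, 10.12 and 130 CPM) and in erythroid-like cells (117, 394, 191 and 438 CPM), whereas in cluster 16 it was highest in c-myb hyper (703 CPM, with 599 in the double mutant). T- or NK-cell-like cells, which carry free RNA of neutrophils, held 14.7 CPM of myb in wild type, 71.2 in c-myb hyper and 182 in the double mutant. The excess of the double mutant over the product of both effects in neutrophil-like cells was 1.16 on the log2 scale (1.06 to 1.26). The pu.1 gene spi1b (ENSDARG00000000767) was higher in the pu.1 G242D/G242D library, at 3347 CPM (3327 to 3366) against 1872 (1851 to 1893) in wild type, 1423 (1410 to 1436) in c-myb hyper and 2370 (2355 to 2385) in the double mutant. Its paralog spi1a stood at 98.6, 160, 73.8 and 99.6 CPM. A missense allele need not alter transcript counts, so the pu.1 labels cannot be checked this way. The gene lbr, whose product shapes the neutrophil nucleus and whose human counterpart is altered in Pelger-Huët anomaly, stood at 57.3 CPM in wild type, 37.2 in c-myb hyper, 61.9 in pu.1 G242D/G242D and 58.5 in the double mutant.

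**Figure D1:**
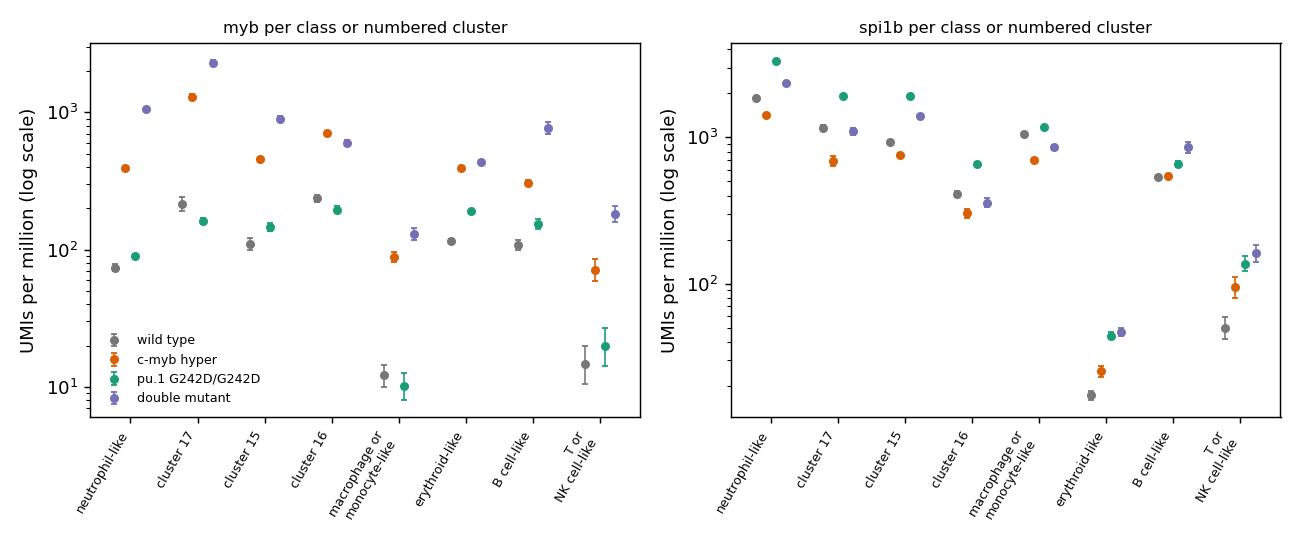
CPM (log axis) of myb and spi1b in each class or numbered cluster, with 1 point per library and bars for the 95% exact Poisson interval. In neutrophil-like cells myb stands at 73.7 CPM in wild type and 1067 CPM in the double mutant.

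Neutrophil-like cells made up a larger share of the marrow in every mutant library, and B-cell-like cells were fewest in the double mutant. Neutrophil-like cells were 29.4% of kept cells in wild type (28.6% to 30.4%), 54.4% in c-myb hyper (53.4% to 55.3%), 58.0% in pu.1 G242D/G242D (57.0% to 59.0%) and 70.7% in the double mutant (69.8% to 71.5%). The ratios to wild type were 1.85 (1.77 to 1.93), 1.97 (1.88 to 2.06) and 2.40 (2.30 to 2.505). With 1 doublet rule for all libraries and a new clustering, part of the neutrophil clusters lost their name, and the log2 ratio of pu.1 G242D/G242D was 0.11 in place of 0.98. With each library clustered alone the log2 ratios were 0.48, 0.67 and 0.29 in place of 0.88, 0.98 and 1.26, which puts the double mutant lowest of the mutants, and the stricter filter gave 1.55 in c-myb hyper and 1.97 in the double mutant. B-cell-like cells were 10.6% (9.98% to 11.2%), 9.87% (9.32% to 10.4%), 4.35% (3.95% to 4.79%) and 0.772% (0.617% to 0.955%). Their share was 2.43-fold lower in pu.1 G242D/G242D (2.16 to 2.73) and 13.7-fold lower in the double mutant (10.96 to 17.3) than in wild type, while in c-myb hyper the ratio of 0.933 had an interval that held 1 (0.857 to 1.02). The size of the B-cell difference varied with clustering and naming: the log2 ratios of pu.1 G242D/G242D and double mutant, -1.28 and -3.78 as reported, were -0.15 and -2.63 under the stricter filter with a new clustering (-1.41 and -3.88 with that filter and the class names kept), -0.40 and -2.90 at resolution 2, and -1.55 and -4.39 at resolution 0.5. The double mutant's B-cell-like share lay below the product of both effects by a log2 departure of -2.39 (-2.75 to -2.03): the product gives 4.06%. Its share was 5.63-fold below pu.1 G242D/G242D and 12.8-fold below c-myb hyper.

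Most B-cell-like cells of wild type lay in clusters 8 and 19, with 593 and 206 cells, and 35 and 3 cells of the double mutant lay there. The cluster led by rag1, the recombinase of developing lymphocytes, held 11.8% of the B-cell-like cells of wild type, 7.88% of c-myb hyper, 27.1% of pu.1 G242D/G242D and 42.9% of the double mutant. Of all kept cells it was 1.25%, 0.778%, 1.18% and 0.331%, so it was smallest in the double mutant. Cluster 23, with rag1 also among its leading genes, held 11.8%, 7.98%, 7.64% and 11.9% of the B-cell-like cells. Erythroid-like cells were 32.7%, 14.1%, 15.2% and 13.1% of the 4 libraries. Their ratios to wild type were 2.32-fold, 2.15-fold and 2.499-fold lower, and the double mutant stood above the product by 1.00 (0.86 to 1.13) on the log2 scale, which turned to -0.25 with each library clustered alone. One erythroid-like cluster is led by heat shock genes (hsp70.3, hsp70.2, hsp70l) and has a median of 839 UMIs. Macrophage-like cells were 6.18%, 2.89%, 4.45% and 1.71%, or 2.14-fold, 1.39-fold and 3.61-fold below wild type, and their departure of -0.28 had an interval that held 0 (-0.60 to 0.03). T- or NK-cell-like cells were 8.46%, 4.39%, 6.92% and 3.81%, again with a departure whose interval held 0. Thrombocyte-like cells were 1.15%, 0.195%, 0.675% and 0.276%, and kidney-epithelium-like cells 1.01%, 0.769%, 0.547% and 1.00%. Shares in 1 library sum to 100%, so a larger neutrophil-like share lowers the others, and the neutrophil-like product of 107% cannot be reached. The 500-UMI limit of the deposited barcodes can set the shares of small cells.

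**Figure D2:**
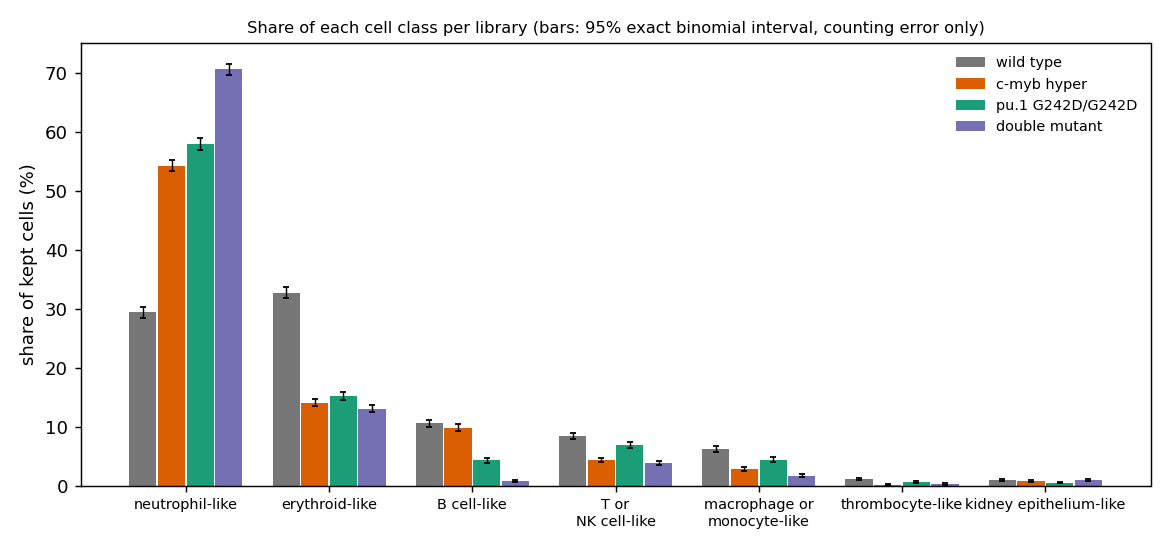
Share of kept cells (%) of each named class in each library, with bars for the 95% exact Clopper-Pearson interval. The B-cell-like share is 10.6% in wild type and 0.772% in the double mutant, and the neutrophil-like share is 29.4% and 70.7%.

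The neutrophil-like class fell into clusters that largely followed the library. Clusters 1 and 6 held 51.4% and 45.2% of the wild-type cells and 34.5% and 10.4% of the c-myb hyper cells, cluster 4 held 53.7% of c-myb hyper, clusters 3 and 10 held 65.3% and 23.4% of pu.1 G242D/G242D, and clusters 0 and 11 held 79.9% and 17.09% of the double mutant. A cluster mostly of 1 library may be that library, not a cell type. Within cluster 1, which wild type and c-myb hyper share, myb stood at 26.3 and 134 CPM and the granule gene lyz at 26440 and 74660 CPM. Within cluster 6 they stood at 89.7 and 660 CPM, and at 82800 and 122000 CPM. Of the 52 genes named by rule in this class, 18 also led 1 of its clusters, among them ptgdsb.1, cldn15lb and tmsb1 (cluster 4), hp and scin (cluster 3), tcf21, capga, ezra, gig2g and spaca4l (cluster 0), rln3a, rdh10b and sstr5 (cluster 11), cox4i1l (cluster 17), alox12 and sc:d156 (cluster 6) and tnfb and mmp13a (cluster 10), so their values describe the same split. The median cell of this class had 4283, 4907, 4598 and 4824 UMIs. Across all 5990 measured genes the median log2 ratio to wild type was -0.11 in c-myb hyper, 0.12 in pu.1 G242D/G242D and -0.02 in the double mutant, and list medians are to be read against these.

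In c-myb hyper neutrophil-like cells, the granule genes lyz and lect2l took more of the transcripts than in wild type, and 8 of 14 measured antigen presentation genes were lower. The gene lyz (ENSDARG00000057789), which encodes lysozyme, stood at 132700 CPM against 60480 in wild type, and the chemotactic granule gene lect2l at 67740 against 25880, which is 2.19-fold and 2.62-fold higher. The myeloid transcription factor gene cebpa was 2.06-fold higher (691 against 335 CPM). The genes named as higher began with the ferritin gene fthl28, at 139 CPM against 4.14, a ratio of 33.5 (26.3 to 43.5), followed by the prostaglandin synthase gene ptgdsb.1 (19.7-fold), the claudin gene cldn15lb (16.1-fold), the antiviral gene gig2g (12.6-fold) and the neutrophil chemokine gene cxcl8a (65.2 against 5.39 CPM, 12.1-fold). The retinol dehydrogenase gene rdh10b was 10.9-fold higher, the transglutaminase gene tgm1l1 9.80-fold, the immune receptor gene dicp2.1 9.01-fold and the arginase gene arg2 7.29-fold, and the immediate early gene jun stood at 69.0 against 7.58 CPM. The genes named as lower were hp, for the hemoglobin-binding haptoglobin, 8.54-fold lower, the sterol regulator insig1 (7.98-fold), the keratin gene krt18b (7.34-fold), the actin-binding afap1l1b (6.72-fold), the tubulin-binding tppp (5.86-fold), the galectin gene lgals9l1 (5.38-fold), sc:d156 (4.29-fold), the lipoxygenase gene alox12 (4.23-fold), the fatty acid carrier gene fabp3 (3.88-fold) and glipr1a (3.29-fold). The symbol hp stands for 2 gene identifiers, which were summed.

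Of the 16 measured neutrophil granule and early effector genes, 5 were higher in c-myb hyper (lect2l, lyz, adam8a, sms and srgn) and 2 lower (mmp13a and scpp8), with a median log2 ratio of 0.34 at percentile 100. Of 12 genes described as MYB-regulated, 5 were higher (myb, lect2l, sgk1, ets2 and hspa4a) and 3 lower (nr4a1, lmo2 and ada), with a median of 0.34 at percentile 99.4. Of 12 myeloid transcription factors, 5 were higher (jun, myb, cebpa, spi1a and klf6a) and 0 lower, with a median of 0.45. Of 14 antigen presentation genes, 8 were lower and 2 higher, with a median of -1.01 at percentile 0, which was -0.43 with members of at least 50 CPM, and their summed CPM was 4538 against 4706 in wild type. In this list psmb8a, a proteasome gene, had 0 UMIs in c-myb hyper against 47.0 CPM in wild type, at least 537-fold lower against the floor of 3 counts, with an interval bound of 436-fold. The genes psmb9a and tap2a of the same pathway had ratios of 0.00110 (0.0000277 to 0.00614), from 1 UMI, and 0.0194 (0.00767 to 0.0408). The ratios of all 3 were under 0.5 in 5 of 5 classes and clusters that could be compared, although in cluster 20, with 0 UMIs of each in c-myb hyper, the intervals of psmb9a and tap2a reach 0.658, and psmb8a stood at 19.09 CPM in the double mutant, which carries the same allele. Of 18 ribosome biogenesis genes 4 were lower and 0 higher, with a median of -0.38 at percentile 0.82. Medians of other lists were: S phase 0.35 (2 of 11 higher), macrophage genes 0.70 (4 of 7 higher, 2 lower), inflammation and immediate early genes 0.19 (-0.19 under the stricter cell filter), p53 and apoptosis 0.28, nuclear envelope and lamina -0.18 with emd, lbr and lmnb2 lower, and PU.1-regulated genes -0.10, which was 0.04 under median-of-ratios scaling. The medians of the NADPH oxidase, stem and leukemia-associated, interferon response, heat shock, glycolysis and oxidative phosphorylation lists were 0.00, -0.01, 0.07, 0.05, 0.00 and 0.04, and their sign changed with the scaling.

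In pu.1 G242D/G242D neutrophil-like cells, several abundant wild-type transcripts were almost absent, and hp and mmp9 were higher. Interferon response genes were lower, as were PU.1-regulated genes over the class as a whole. The thymosin gene tmsb1, which encodes an actin-binding protein, stood at 9.92 CPM against 1327 in wild type, 134-fold lower (120 to 149), and the lysozyme-like gene lygl1 at 8.25 against 515, 62.3-fold lower. No UMI of sc:d156 was counted, against 80.5 CPM in wild type, at least 917-fold lower against the floor of 3 counts, with an interval bound of 745-fold. The other genes named as lower were rpz5 (225-fold), the sugar transporter gene slc2a6 (151-fold), the TNF receptor gene tnfrsf9b (64.0-fold), the adaptor gene card9 of fungal sensing (56.8-fold), tppp (54.8-fold), the chloride channel gene clic2 (24.5-fold) and lgals9l1 (25.6-fold). Among the genes named as higher were hp (3402 against 101.7 CPM, 33.4-fold, 31.8 to 35.1), the actin-severing scin (108-fold), the protease inhibitor genes spink2.2 and spink2.4 (59.7-fold and 34.5-fold), the lectin gene itln1 (24.2-fold, 578 CPM), the relaxin gene rln3a (21.7-fold), cox4i1l (21.8-fold), the cystatin gene cst14b.2 (16.3-fold, 472 CPM) and spaca4l (15.4-fold). Of these, spink2.2, spink2.4, itln1 and cst14b.2 are leading genes of the unnamed cluster 25. It held 0, 0, 89 and 103 cells of wild type, c-myb hyper, pu.1 G242D/G242D and double mutant, so their values here can hold RNA of its cells. However, spink2.2 and spink2.4 also lead the unnamed cluster 12, which held 274, 856, 54 and 96 cells in that order. Cells that carry spink2.2 and spink2.4 were thus not missing from wild type. The gelatinase gene mmp9 was 3.59-fold higher (4326 against 1206 CPM).

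Of 19 measured genes described as PU.1-regulated, 10 were lower in pu.1 G242D/G242D and 0 higher, with a median log2 ratio of -0.67 at percentile 0. The lower members included the Fc receptor chain gene fcer1g (14.2-fold), the NADPH oxidase gene cybb (3.23-fold), il1b, an inflammatory cytokine gene (2.13-fold), lyz (1.81-fold, and 3.66-fold without cluster 17) and the myeloperoxidase gene mpx (1.82-fold). Of 16 interferon response genes 12 were lower and 0 higher, with a median of -1.20 at percentile 0, led by irf1b (51.0 against 381 CPM, 7.46-fold) and gbp1 (3.81-fold). Of 14 antigen presentation genes 7 were lower and 0 higher, with a median of -0.63 at percentile 0.03, among them the invariant chain genes cd74a (4.21-fold) and cd74b (2.67-fold). The 14 NADPH oxidase and receptor genes had 5 lower (cyba, cybb, il6r, ncf1 and ncf4) and 1 higher, the chemokine receptor gene cxcr1 (2.33-fold), with a median of -0.15. The 16 granule genes had 5 lower (timp2b, cpa5, lyz, mpx and npsn) and 4 higher (mmp9, adam8a, mmp25b and sms), with a median of -0.21 that was 0.08 under the stricter cell filter. Of 18 glycolysis genes 5 were higher (aldocb, pgam1a, gpia, hk1 and eno1a) and 1 lower (hk2), with a median of 0.42 at percentile 100. S phase genes had 4 of 11 higher, with a median of 0.37, and stem and leukemia-associated genes had 3 of 8 higher (lmo2, mcl1b and bcl2l1), with a median of 0.24. Within cluster 17 alone, 0 of 23 S phase genes were higher and 9 lower, with a median of -0.44. That cluster made up 10.06% of this class in pu.1 G242D/G242D and 2.26% in wild type, so the S phase value of the class also depends on its make-up. Macrophage genes had a median of -0.42, which was 0.03 after thinning to 1000 UMIs. The medians of the heat shock and oxidative phosphorylation lists were 0.20 and 0.16. Those of the MYB-regulated, myeloid transcription factor, nuclear envelope, inflammation, p53 and ribosome biogenesis lists (0.17, 0.11, -0.04, 0.09, -0.01 and 0.07) changed sign under at least 1 scaling, depth or filter. Within the nuclear envelope list, lmnb1 was 3.25-fold lower, and banf1 and syne2b were lower too. Cluster 17 holds 544 of these 5406 cells with a median of 15660 UMIs, and the higher values of capga and gig2g in pu.1 G242D/G242D, 1.36 and 0.72 on the log2 scale, were both -0.92 without it. No other cluster of this class held at least 50 cells of both libraries (66 of wild type). Within it, 3 of 18 PU.1-regulated genes were higher and 4 lower, with a median of 0.155, against 0.141 for all measured genes. Granule genes had 8 of 16 higher and 1 lower there (median 0.61). Interferon response genes had 3 of 12 lower and 0 higher (median -0.42).

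In double-mutant neutrophil-like cells, lect2l and lyz were higher than in wild type as in c-myb hyper, and most of the genes almost absent in pu.1 G242D/G242D were almost absent too. The gene lect2l stood at 90880 CPM, 3.51-fold above wild type and above all other libraries, and lyz at 95890 CPM, 1.59-fold above wild type and below c-myb hyper. The genes slc2a6, tnfrsf9b, tppp, card9, lygl1 and rpz5 were 416-fold, 222-fold, 194-fold, 142-fold, 103-fold and 109-fold lower than in wild type. The gene sc:d156 had 3 UMIs in 7685 cells, a ratio of 0.000926 (0.000191 to 0.00271). The glycine transporter gene slc6a9 was 507-fold lower, marcksl1b, for an actin-linked membrane protein, 97.8-fold (12.2 against 1188 CPM), and fcer1g 96.3-fold. Among the higher genes were the actin-capping capga (129-fold), the vimentin-like viml (103-fold), the transcription factor gene tcf21 (61.5-fold, 96.3 CPM), the complement gene c1qb (49.7-fold, 118 CPM), the somatostatin receptor gene sstr5 (40.1-fold), the NK-lysin gene nkl.1 (39.2-fold), the ezrin gene ezra (36.13-fold), sh2d1ab (33.29-fold) and cst14b.2 (29.5-fold, 855 CPM). The gene viml is also on the kidney list of the free RNA check. Both viml and cst14b.2 are leading genes of the unnamed cluster 25. Since that cluster held 0 wild-type and 103 double-mutant cells, the value of cst14b.2 here can hold RNA of its cells. For viml, the log2 ratio of c-myb hyper, with 0 cells of that cluster, was above that of pu.1 G242D/G242D, with 89. The viml values thus do not follow the number of those cells, though the double-mutant value can hold some of their RNA.

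Some genes in the double mutant lay outside the range of the other 3 libraries. The genes named as highest were viml, nkl.1, c1qb, tcf21 and the disulfide isomerase gene pdia2 (103 CPM against 12.9 in c-myb hyper and 19.6 in pu.1 G242D/G242D). The lowest were slc6a9, the junction gene f11r.1 (1.29 CPM against 51.5, 36.6 and 27.5), the cytokine gene tnfb (4.85 against 173, 67.0 and 78.2), the collagenase gene mmp13a (190 against 4190, 2174 and 3038) and the receptor gene il10ra (1.76 against 50.6, 27.96 and 24.6). The transcription factor gene cebp1 stood at 167 CPM against 54.5, 65.5 and 94.6, cebpa at 992 against 335, 691 and 243, and mycb at 28.8 against 4.01, 5.42 and 2.37.

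All 14 measured antigen presentation genes were lower in the double mutant than in wild type, with a median log2 ratio of -1.50 at percentile 0. Of 19 PU.1-regulated genes 13 were lower and 2 higher (cebpa and lyz), with a median of -1.13 at percentile 0, and against the c-myb hyper and pu.1 G242D/G242D libraries the medians were -0.70 and -0.62. Of 12 MYB-regulated genes 8 were higher (myb, mycb, sgk1, lect2l, hspa4a, mat2aa, nr4a1 and ets2) and 1 lower (lmo2), with a median of 1.02 at percentile 100. Of 12 myeloid transcription factors 7 were higher and 1 lower (junba), with a median of 0.67. Of 14 NADPH oxidase and receptor genes 8 were lower and 1 higher (cxcr4b), with a median of -0.66 at percentile 0.51. Of 21 inflammation and immediate early genes 10 were lower (led by cxcl11.1, tnfb, acod1 and il1b) and 6 higher (led by cxcl8b.1 and jun), with a median of -0.50. Of 16 granule genes 6 were higher and 7 lower, with a median of -0.30 at percentile 20.4, although their summed CPM was 1.87-fold higher, since lect2l and lyz make up most of it. Of 16 interferon response genes 6 were lower and 2 higher, with a median of -0.46, which is 0.37 against pu.1 G242D/G242D. Ribosome biogenesis genes had a median of 0.37 (6 of 18 higher) and heat shock genes of 0.40 (3 of 11 higher), and both were below 0, at -0.13 and -0.08, with members of at least 50 CPM. The S phase, stem, nuclear envelope, macrophage, p53, glycolysis and oxidative phosphorylation lists had medians of 0.01, -0.03, 0.00, 0.01, 0.10, 0.12 and -0.05, and among these only that of glycolysis kept its sign under all alternatives. Of the G2 and M phase genes 2 were measured in this class, with cks2 higher and anln lower in each mutant. Cluster 17, with 66 wild-type and 63 double-mutant cells, was the only cluster of this class with at least 50 cells of both. Within it, 5 of 12 antigen presentation genes were lower and 0 higher, with a median of -0.88, against -0.10 for all measured genes. PU.1-regulated genes had 11 of 18 lower and 0 higher there (median -0.75). Interferon response genes had 2 of 12 lower and 1 higher (median -0.0055).

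**Figure D3:**
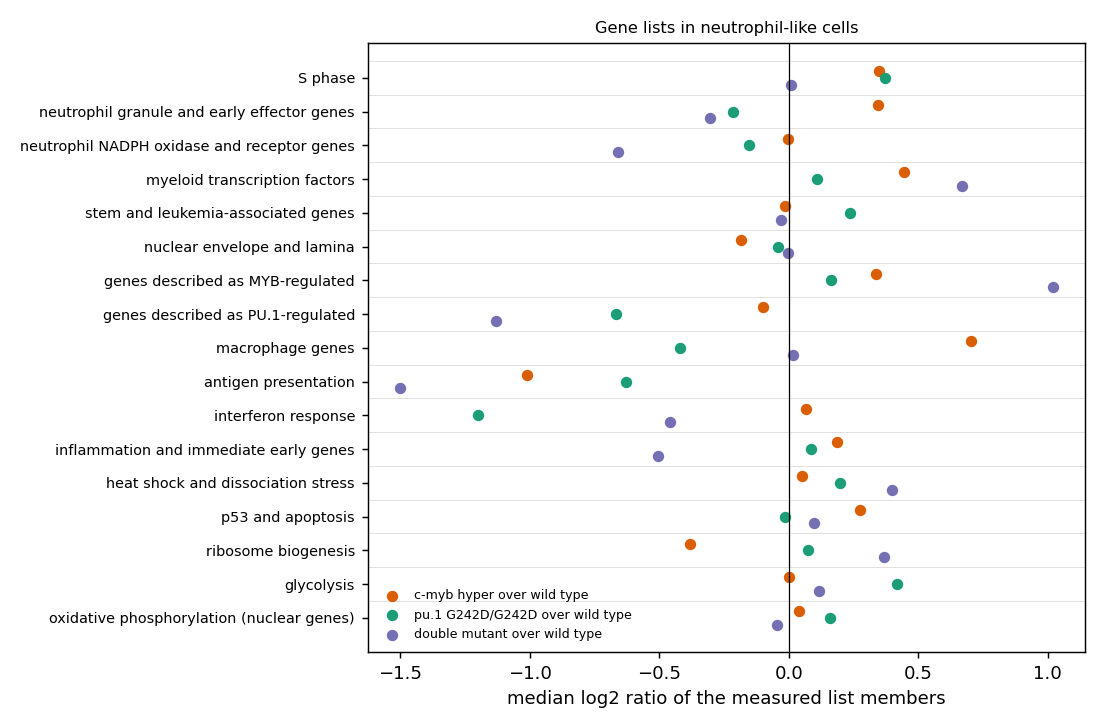
Median log2 ratio to wild type (x axis) of the measured members of each gene list in neutrophil-like cells, with 1 point per mutant library. PU.1-regulated genes lie at -0.10, -0.67 and -1.13 in c-myb hyper, pu.1 G242D/G242D and double mutant, and antigen presentation genes at -1.01, -0.63 and -1.50.

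Free RNA differed between the libraries. Hemoglobin genes, which neutrophils should lack, were lower in the neutrophil-like cells of each mutant, with hbaa1 at 2733 CPM in wild type and 1017, 546 and 592 CPM in c-myb hyper, pu.1 G242D/G242D and double mutant. All 4 measured members were lower in pu.1 G242D/G242D and the double mutant, and 3 of 4 in c-myb hyper. Granule RNA was higher in c-myb hyper and the double mutant: lyz in T- or NK-cell-like cells stood at 2273 CPM in wild type, 8878 in c-myb hyper and 5033 in the double mutant, with a UMI in 64.6%, 100% and 98.8% of these cells. The pu.1 G242D/G242D library differed by gene and class: lyz stood at 2208 CPM in T- or NK-cell-like cells, at 297 against 464 in erythroid-like cells and at 2058 against 782 in B-cell-like cells, and lect2l was above wild type in all 3 (1443 against 819, 371 against 178 and 1556 against 477 CPM). The immunoglobulin check list had 1 measured gene in neutrophil-like cells, ighv1-4, with log2 ratios of -1.01, 2.42 and -0.26, and the kidney list 1, viml, with 3.49, 1.60 and 6.68.

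Cluster 16, deep cells led by cdk6, nanos1 and csf1rb, has 3 progenitor markers among its top 30 genes, and the erythroid-like cluster 13 has 4. Cluster 16 held 287, 123, 295 and 132 cells of the 4 libraries. In c-myb hyper, DNA replication genes were higher there: 16 of 23 S phase genes were higher and 0 lower, with a median log2 ratio of 1.00 at percentile 100. Hemoglobin genes summed to 21330 CPM in the wild-type cells of this cluster and to 949, 3380 and 595 CPM in c-myb hyper, pu.1 G242D/G242D and double mutant. Free RNA subtraction is scaled by hemoglobin, so ratios after it, such as those of mmp13a below, depend on this difference. The genes named as higher were the keratin genes krt18a.1 (16.99-fold) and krt8 (2.72-fold), the nucleotide hydrolase gene dut (3.88-fold), the plectin genes plecb (3.66-fold) and pleca (2.63-fold), lect2l (3.01-fold), myb (703 against 238 CPM, 2.96-fold), the peroxiredoxin gene prdx1 (2.89-fold), icn (2.69-fold) and cox6a2 (2.65-fold). Lower were the carbonic anhydrase gene cahz of red cells (14.9-fold), hp (8.10-fold), the translation regulator gene nanos1 (3.73-fold), the kinase gene pik3c2b (3.09-fold), the mannose receptor gene mrc1b (2.87-fold), mmp13a (2.63-fold, but 4.06 on the log2 scale after free RNA was subtracted), gbp2 (2.62-fold), myh9a (2.26-fold), calcoco2 (2.23-fold) and the class II gene mhc2a (2.09-fold). Of 24 oxidative phosphorylation genes 5 were higher, with a median of 0.40, and of 10 MYB-regulated genes 6 were higher and 1 lower, with a median of 0.72.

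In pu.1 G242D/G242D, cluster 16 had higher hp (3.62-fold), anxa2a (4.09-fold), ascc1 (3.51-fold), ponzr6 (3.33-fold), lect2l (3.32-fold), mmp9 (3.15-fold), the metal-binding mt2 (2.75-fold), icn (2.73-fold), cox6a2 (2.65-fold) and the amino acid transporter gene slc7a3a (2.52-fold). Lower were cahz (4.34-fold), the interferon-induced gbp2 (3.22-fold) and irf1b (2.76-fold, 206 against 567 CPM), farsa (2.11-fold), mhc2b (1.94-fold), ifi46 (1.94-fold), pik3c2b, tapbp.1 and the chromatin gene hmgb3a (1.85-fold each) and mhc2a (1.68-fold). Of 14 interferon response genes 7 were lower and 0 higher, with a median of -0.58 at percentile 0, and of the 23 S phase genes 5 were higher and 0 lower, with a median of 0.34 at percentile 100. In the double mutant lect2l was 14.8-fold higher than in wild type (2451 against 166 CPM), krt18a.1 12.7-fold, ponzr6 6.76-fold, grn1 5.41-fold, mafbb 4.52-fold, icn 4.38-fold, the survival kinase gene pim2 4.25-fold, cox6a2 4.05-fold, ascc1 3.51-fold and lyz 3.05-fold. Lower were cahz (19.4-fold), mmp13a (10.11-fold, but 2.89 on the log2 scale after free RNA was subtracted), nanos1 (5.25-fold), gbp2 (3.99-fold), gig2i (3.47-fold), ifi45 (2.91-fold), hp (2.63-fold), tnrc18 (2.62-fold), mt2 (2.42-fold) and irf1b (2.39-fold). Above all other libraries were lect2l, pim2, grn1, lyz and myca (143 CPM against 63.4, 50.4 and 41.4), and below all were gig2i, mmp13a, ifi45, mt2 and oaz1b. Of the 23 S phase genes 1 was higher and 4 lower in the double mutant, with a median of 0.01. Since free lect2l and lyz RNA differ between the libraries, their levels here can hold background: lect2l stood at 819, 4589, 1443 and 4737 CPM in T- or NK-cell-like cells and at 166, 499, 551 and 2451 CPM in cluster 16.

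Cluster 15, cycling cells with high mki67 and top2a that carry lyz, held 194, 271, 297 and 221 cells. Of 33 measured G2 and M phase genes, 12 were higher in c-myb hyper, 9 in pu.1 G242D/G242D and 21 in the double mutant, and 0 lower in any, with medians of 0.43, 0.35 and 0.82. Of 32 S phase genes, 6, 8 and 20 were lower and 0 higher, with medians of -0.10, -0.34 and -0.71. The gene myb stood at 110, 455, 146 and 901 CPM there and lect2l at 6671, 23260, 23250 and 46280 CPM.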

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

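All tests below were written down before their results were seen, except those of B-cell-like cells per T- or NK-cell-like cell and of doublets kept, and both tests on psmb8a, psmb9a and tap2a, which were chosen after the result was seen.

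Some gene lists in neutrophil-like cells moved one way with an allele alone and the opposite way with it in the presence of the other allele. This difference between genotypes was not tested, since each is 1 library. It is the departure of the double mutant, so by construction it is the same for either allele. For S phase genes the summed CPM had a log2 ratio of 0.50 for c-myb hyper over wild type. It was -0.23 for the double mutant over pu.1 G242D/G242D, a difference of -0.73. The pu.1 allele gave 0.36 and -0.37. The change of sign for the c-myb allele was not kept without cluster 17, where the summed CPM of the 7 members still measured was 215 in pu.1 G242D/G242D and 218 in the double mutant, and the difference was -0.56. Within cluster 17 alone, S phase genes summed to 468 CPM in pu.1 G242D/G242D against 622 in wild type, opposite to the class. Inflammation and immediate early genes gave 0.14 and -1.26 for the c-myb allele and 0.59 and -0.80 for the pu.1 allele, both a difference of -1.39. Macrophage genes gave 0.67 and -0.14 for the c-myb allele, a difference of -0.81. Stem and leukemia-associated genes gave 0.12 and -0.47 for the c-myb allele and 0.17 and -0.41 for the pu.1 allele, a difference of -0.59 each. The p53 and apoptosis genes gave 0.25 and -0.14, and 0.04 and -0.35, a difference of -0.39 each. The NADPH oxidase and receptor genes gave 0.09 and -0.14 for the c-myb allele, a difference of -0.23, and the nuclear envelope genes -0.11 and 0.05 for the pu.1 allele, a difference of 0.17 that was 0.07 without cluster 17. Summed CPM follows the most abundant members, so these values can differ in sign from list medians.

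The 10 genes named as lower, headed by sc:d156, rpz5 and tmsb1, were at least 24.5-fold lower in pu.1 G242D/G242D neutrophil-like cells. In macrophage-like cells the median log2 ratio of these 10 genes was -0.85, and 9 of them were less than 4-fold lower. For the genes as a set this argues against a sequence or counting difference between the fish. It stays open for sc:d156 (10.5-fold lower there) and lgals9l1 (3.77-fold, 3.26 to 4.38). In macrophage-like cells lgals9l1 stood at 103 CPM in wild type, 27.4 in pu.1 G242D/G242D, 13.5 in c-myb hyper and 25.3 in the double mutant. After free RNA subtraction the median of the 10 genes in neutrophil-like cells was -6.54 and after thinning to 1000 UMIs -6.40. Neither free RNA nor depth per cell thus accounts for their lower values. All 10 were also lower than wild type in the double mutant, by 9.70-fold (lgals9l1) or more. An effect of the pu.1 allele and a difference between the fish that acts in neutrophils both stay open, since each genotype is 1 library and no biological explanation was tested.

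The B-cell-like share of the double mutant was 13.7-fold below wild type, a log2 ratio of -3.78 that was -2.63 under the stricter filter with a new clustering. B-cell-like cells per T- or NK-cell-like cell were lower too, with a ratio of 0.162 (0.126 to 0.209), which argues against mere dilution by neutrophil-like cells. The share ratio was 0.0730 among cells of at least 2000 UMIs and 0.0697 with doublets kept, and cd79a, cd79b and pax5 UMIs over all cells had a CPM ratio of 0.0843 (0.0659 to 0.107), so small cells, doublet calls and cluster names do not account for it either. An effect of the alleles and variation between fish, of unknown number per library, both stay open, since there are no replicate libraries and no biological explanation was tested.

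The genes psmb8a, psmb9a and tap2a were almost absent in c-myb hyper. The ratios of all 3 were under 0.5 in all 5 classes and clusters with enough counts, as a different haplotype of their locus in that fish would give, although the intervals of psmb9a and tap2a in cluster 20 reach 0.658, while the median of interferon response genes was 0.067, which argues against a lower interferon response as the cause. The double mutant, with the same c-myb allele, held 19.09 CPM of psmb8a in neutrophil-like cells, against 46.95 in wild type. It held 42.5, 59.4 and 104 CPM in macrophage-like, B-cell-like and T- or NK-cell-like cells, against 45.5, 46.2 and 47.2 in wild type. In cluster 20 it held 10.2 against 32.9 CPM. A background difference of the fish is thus a candidate explanation, and the antigen presentation median of c-myb hyper partly rests on these genes.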

How the results depend on the processing

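No paired analysis was run, each genotype has 1 library, and no result comes from a test. Alternatives chosen after seeing the data were the same doublet rule in every library, the stricter filter and that doublet rule with the class names of the reported clustering, and the neutrophil-like class without cluster 17. Unless a reason is given below, the cause was not tested. Values are log2 ratios to wild type in the order c-myb hyper, pu.1 G242D/G242D, double mutant, where not said otherwise.

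For the neutrophil-like share (0.88, 0.98 and 1.26 as reported) all 10 alternatives per mutant kept the direction, with ranges of 0.48 to 1.55, 0.11 to 1.00 and 0.29 to 1.97. The B-cell-like share of the double mutant (-3.78) stayed between -4.39 and -2.63 and that of pu.1 G242D/G242D (-1.28) between -1.63 and -0.15, while that of c-myb hyper (-0.10) ranged from -0.47 to 0.23. For myb in neutrophil-like cells all 12 alternatives per mutant were above 0. The medians of antigen presentation and of PU.1-regulated genes stayed below 0 in pu.1 G242D/G242D and the double mutant under all 13.

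The stricter filter (500 genes, 5% mitochondrial UMIs) gave neutrophil-like shares of 1.55 in c-myb hyper and 1.97 in the double mutant and B-cell-like shares of -0.24, -0.15 and -2.63. With each library clustered alone the neutrophil-like shares were 0.48, 0.67 and 0.29, the B-cell-like shares 0.23, -0.80 and -3.44, and the departure of the erythroid-like share, 1.00 as reported, turned to -0.25. With the same doublet rule in every library the neutrophil-like shares were 0.80, 0.11 and 1.18, and their departure, -0.60 in the reported clustering, turned to 0.27. With the class names kept, the stricter filter gave 0.81 in c-myb hyper, and that doublet rule 0.81 in c-myb hyper and 1.18 in the double mutant. A denominator without erythroid-like and thrombocyte-like cells gave 0.51, 0.63 and 0.87 for neutrophil-like and -0.47, -1.63 and -4.17 for B-cell-like cells, by construction, since these cells differ between the libraries. Resolution 2 gave B-cell-like shares of -0.40, -0.40 and -2.90, and resolution 0.5 gave -1.55 in pu.1 G242D/G242D and -4.39 in the double mutant.

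In neutrophil-like cells, myb (2.41, 0.28 and 3.85 as reported) was 2.55 in c-myb hyper and 0.18 in pu.1 G242D/G242D under median-of-ratios scaling. It was 2.25 in c-myb hyper when hemoglobin, immunoglobulin, mitochondrial and ribosomal genes were left out of the total. The mean of per-cell CPM gave 2.73, 0.52 and 4.36, thinning to 1000 UMIs gave 2.74, 0.46 and 4.33, and the class without cluster 17 gave 2.58, 0.0505 and 4.08. Thinning left out 187, 564, 142 and 298 shallower cells of wild type, c-myb hyper, pu.1 G242D/G242D and double mutant.

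Granule genes (0.34, -0.21 and -0.30) had medians of 0.48 in c-myb hyper and -0.32 in pu.1 G242D/G242D under median-of-ratios scaling, and of 0.19, -0.18 and -0.36 with those 4 kinds of genes left out. They had medians of 0.56, -0.33 and -0.14 after thinning, of -0.31 and -0.12 in pu.1 G242D/G242D and the double mutant as means over cells, and of 0.077 and -0.12 there under the stricter filter. In the double mutant their median was -0.34 after free RNA subtraction and under the stricter filter with the class names kept, and -0.35 without cluster 17.

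PU.1-regulated genes (-0.10, -0.67 and -1.13) had medians of 0.20, -0.57 and -0.89 with members of at least 50 CPM, of 0.038 in c-myb hyper and -0.78 in pu.1 G242D/G242D under median-of-ratios scaling, and of -0.25 in c-myb hyper and -1.18 in the double mutant with the 4 kinds of genes left out. In pu.1 G242D/G242D they were -0.84 both as means over cells and after thinning, -0.55 under the stricter filter and -0.60 without cluster 17, and in the double mutant -1.19 under the stricter filter.

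Antigen presentation genes (-1.01, -0.63 and -1.50) had medians of -0.43, -0.49 and -1.30 with members of at least 50 CPM, and of -1.41, -1.04 and -1.82 under the stricter filter. In c-myb hyper they were -0.73 under median-of-ratios scaling, -1.17 with the 4 kinds of genes left out, -0.89 after thinning and -0.82 with the same doublet rule and the class names kept. In pu.1 G242D/G242D they were -0.88 under median-of-ratios scaling, -0.75 as means over cells and -0.49 without cluster 17, and in the double mutant -1.84 as means over cells and -1.67 after thinning.

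Reversed in neutrophil-like cells were, besides the granule median of pu.1 G242D/G242D, the inflammation median of c-myb hyper (0.19, but -0.19 under the stricter filter) and, with members of at least 50 CPM, the heat shock and ribosome biogenesis medians of the double mutant (-0.077 and -0.13). In pu.1 G242D/G242D, c1qb was 0.86 and fthl28 -0.18 after thinning, and capga, fthl28 and gig2g were -0.92, -0.49 and -0.92 without cluster 17, whose cells thus carry their higher values. In cluster 16, for c-myb hyper, the myeloid transcription factor median was -0.0375 with the 4 kinds of genes left out, -0.092 as means over cells and -0.11 after thinning, and the inflammation median was -0.45 as means over cells. There mmp13a was 4.06 after free RNA subtraction and 1.62 under the same doublet rule, mmp9 0.44 with doublets kept and 0.15 under that rule, grn1 0.21 after thinning and 0.71 under the stricter filter, and farsa 0.11 after thinning. Also in cluster 16, the MYB-regulated median of pu.1 G242D/G242D was -0.084 after thinning, and in the double mutant mmp13a was 2.89 after free RNA subtraction and prdx1 -1.48 after thinning.

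Of all 3456 alternative values of single genes, 3387 kept the sign of the reported value, as did 1204 of 1341 of list medians and 193 of 200 of share ratios. The single genes were those named by rule, with myb, spi1b, spi1a and lbr. Most were thus chosen for a large difference in these same counts, so a kept sign is a weak check for them. Depth limits the smaller classes: the double mutant holds 84 B-cell-like cells and 132 cells of cluster 16, and thinned cluster 16 values rest on 123000 to 294000 UMIs per library.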

Other observations

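Macrophage-like cells, mostly of cluster 9 in every library (88.6%, 82.9%, 98.1% and 98.9% of the class), differed in cell cycle and interferon genes. In c-myb hyper, 14 of 15 measured S phase genes and 6 of 6 G2 and M phase genes were higher than in wild type, with median log2 ratios of 1.26 and 1.59, and 9 of 18 macrophage genes were higher and 3 lower. In pu.1 G242D/G242D, 12 of 17 interferon response genes were lower and 0 higher, with a median of -1.42 at percentile 0, and 9 of 15 antigen presentation genes were lower. In the double mutant, 17 of 26 inflammation and immediate early genes were higher and 1 lower, with a median of 0.73, and 10 of 17 interferon response genes were lower, with a median of -0.75.

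Erythroid-like cells of pu.1 G242D/G242D had all 20 measured ribosome biogenesis genes higher than in wild type, with a median log2 ratio of 0.98, and 13 of 14 glycolysis genes higher, with 1.13, against 0.498 for all 3452 measured genes. Summed hemoglobin CPM there was 248900 against 462700 in wild type, and cluster 13 made up 28.8% of the class against 11.8%. In the same cells 19 of 21 G2 and M phase genes were lower, with -1.17. The double mutant had 16 of 21 G2 and M phase genes lower and none higher, with -0.90, and ribosome biogenesis at -0.26. Cluster 14, whose leading genes include cell division genes, held 21.02%, 13.3%, 9.50% and 7.65% of this class in the 4 libraries. In B-cell-like cells S phase genes were lower in pu.1 G242D/G242D (27 of 32, median -1.07) and in the double mutant (14 of 32, with 1 higher, median -0.86), with the latter resting on 84 cells. Cluster 23, with mki67 among its leading genes, was 11.8% of this class in wild type, 7.64% in pu.1 G242D/G242D and 11.9% in the double mutant. Depth differed too, with 3473, 7871 and 5920 UMIs in the median cell. T- or NK-cell-like cells of the double mutant had 16 of 23 inflammation and immediate early genes higher and 1 lower, at percentile 100, and 9 of 18 interferon response genes higher and 1 lower, with 0.68. In these T- or NK-cell-like cells cluster 26 made up 14.5% against 1.43% in wild type, and 9 of 15 granule genes were higher and 2 lower, with a summed CPM of 16310 against 5872. That sum can be free RNA of neutrophils: lyz stood there at 5033 against 2273 CPM and lect2l at 4737 against 819. Scaling alternatives were not run in these classes.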
